A study of Mus musculus with 16 samples.

How the data were processed

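The series profiled macrophages sorted from mouse gliomas on 16 Affymetrix 3' expression arrays, 1 array per mouse. Per the labels' protocols, tumours were started by intracranial injection of cells that release a retrovirus carrying PDGF-B into mice whose Nestin-positive cells can be infected and which lack Ink4a/Arf. Mice with a tumour of 4.5 to 40 mm3 on MRI were assigned at random to BLZ945, an inhibitor of the CSF-1 receptor kinase, or to its vehicle, once per day by gavage for 7 days. The labels give the dose as 200 mg without a body weight. Tumours were dissociated with papain, cells positive for CD11b and negative for Gr1 were sorted, and 75 ng of total RNA per mouse was amplified and labelled. Sex, age and an initial tumour volume, the last without a unit, are labelled per mouse, and the volume is missing for 2 Vehicle mice.

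The deposited values are on a log2 scale, 1 per probe set and array, as their range and shape show. The submitters' processing notes name GCOS 1.4 and RMA without saying which step each performed, and the RMA implementation, the array annotation and a genome build are not given in the sources used here. RMA corrects the background, normalizes across arrays and summarises the probes of a probe set. It compresses differences of dim probe sets, so changes of weakly expressed genes are understated. The authors' log2 values were used as deposited. No scanner intensities were analysed here, so no probe set could be called above or below background, and the number of arrays limits the precision.

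Each of 22690 probe sets was named through the platform annotation, with symbols looked up by gene identifier in a RefSeq gene table. Exactly 1 symbol was held by 20393 probe sets, several by 691 and none by 1606, of which 51 were array controls. The lookup found 20364 of the 20393 and altered 0 symbols. No gene was named from a probe set with several symbols. For each of 12394 genes the probe set with the highest mean over all 16 arrays was tested, and 4958 genes had more than 1. No filter on dim probe sets was applied.

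Groups were taken from the agent in the sample labels, with 8 mice each. The values of the arrays were compared before averaging, and the highest correlation between 2 arrays was 0.991, so no array was counted as a repeat of another. BLZ945 was compared with Vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), and a gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05. A second count asked for a change of at least 2-fold, which is a log2 change of 1. Other fits tested sex with the agent as covariate, the interaction of agent and sex, the older against the younger BLZ945 mice, and the slope on log2 initial tumour volume within BLZ945. Adjusted p-values of single genes are limma's throughout. Differences in log2 are BLZ945 minus Vehicle, and levels are means ± SD over 8 mice.

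There were 17 lists of genes and 13 lists of cell type markers, fixed before the data were examined, as were the comparisons and the rule for named genes. The lists were tested as 2 families with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over its family. In subsets of mice and with covariates camera was run at the preset correlation alone. An exact two-sided permutation test of each list's mean over all 12870 labellings of the mice was added after the data were seen. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Arg1, Mrc1, Adm, F13a1 and Serpinb2 are genes the study itself picked from these samples, so the lists that hold them are not independent evidence of a direction.

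Named genes are the 10 with the largest rise and the 10 with the largest fall among changed genes, up to 4 changed members per list with the smallest p or else the 2 with the smallest p, 15 genes fixed in advance, the leading genes of the other fits, and the 2 brightest members of each marker list. Genes outside this rule are identified as chosen after their values were seen.

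The calculations were tested on simulated data with the real genes' means and spreads. With the design of the agent comparison over 12394 genes, limma recovered 41.8% of genes changed by 0.5, 83.6% of those changed by 1 and 98.5% of those changed by 2 log2 units. The interaction fit recovered 20.9% at 1 and 75.8% at 2 log2 units, the age fit 62.7% and 89.4%, and the volume slope 50.8% and 93.9%. Camera at the preset correlation called 3 of 3 shifted lists and 0 of 14 others. The simulated genes varied independently of each other, unlike real list members, so this does not show how often camera calls unchanged lists. In other splits of the real mice, given below, it called a median of 5 lists. Alternatives covered the choice of probe sets, dim genes, further normalization, eBayes settings, array weights, covariates for sex, age, tumour volume and array properties, subsets of mice, a replicate block, a plain test per gene and leaving out each mouse. A gene or list that passed only with a mouse left out is reported as depending on that mouse, not as changed. Some list members were not analysed here because no probe set names them alone.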

Results

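The data are expression profiles of tumour-associated macrophages, sorted as CD11b-positive and Gr1-negative cells, from 16 glioma-bearing mice, 8 given BLZ945 and 8 given vehicle for 7 days. There were 9 female mice, 4 in the Vehicle group and 5 in the BLZ945 group, and 7 male mice. Only the age of 11.29 weeks held both agents, with 4 mice each, and 4 BLZ945 mice were 13.14 weeks old. The labelled initial tumour volume, whose unit the label does not give, was 17.8 ± 6.38 in 6 Vehicle mice and 78.2 ± 30.6 in 8 BLZ945 mice (SD, exact two-sided permutation p = 0.000999). The ranges, 11.9 to 27.3 and 41.3 to 132.3, did not overlap. If the label is in the mm3 of the protocol, 8 BLZ945 mice and 0 Vehicle mice exceeded the enrolment limit of 40 mm3. The spread of an array's log2 values had a mean SD of 2.39 ± 0.0705 in Vehicle and 2.33 ± 0.0824 in BLZ945 (n = 8 each, exact permutation p = 0.149). The first principal component, 31.95% of the variance, followed that spread (r = -0.951, rho = -0.894, permutation p = 1e-05, the smallest 100000 permutations can give, and 3e-05). Without the 2 arrays farthest from the median, r was -0.926. With 3 relations computed, the adjusted values were 3e-05 and 9e-05.

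The first comparison asks what inhibition of the CSF-1 receptor does to the expression profile of macrophages that remain in the tumour. In BLZ945, 28 of 31 cell cycle genes fell, 7 of 25 genes of alternative activation fell and 1 rose, and 6 of 18 genes of disease-associated microglia rose. The calls of these 3 lists were lost with an estimated correlation, with adjusted p = 0.0503, 0.0664 and 0.0503. Adm, which encodes the vasodilator peptide adrenomedullin, fell by 3.44 log2 units, from 6.90 ± 1.01 to 3.46 ± 0.21 (SD, n = 8 each, adjusted p = 1.03e-05). F13a1, the catalytic subunit of a coagulation factor, fell by 3.41, from 8.98 ± 0.67 to 5.57 ± 0.73 (adjusted p = 8.26e-06), and the mannose receptor gene Mrc1 fell by 3.08, from 9.45 ± 0.62 to 6.38 ± 1.15 (adjusted p = 0.000171). Rrm2, a subunit of ribonucleotide reductase, fell by 3.29 and the proliferation marker Mki67 by 2.84. Igf1, a growth factor, rose by 1.56 and the lipoprotein lipase gene Lpl by 1.42, each higher in 8 of 8 BLZ945 mice than in any Vehicle mouse.

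Of 12394 genes, 984 changed, 322 higher and 662 lower in BLZ945. At least a 2-fold change was seen in 273, of which 55 were higher and 218 lower. The groups did not overlap in 167 changed genes, 39 higher and 128 lower, where chance gives 0.0155% of genes. Among the 486 changed genes with several probe sets, 0 had probe sets called in opposite directions. The other large falls were in Hspa1b (-2.83), an inducible heat shock protein, Fabp7 (-2.76), a fatty acid-binding protein of glial progenitors, Bub1 (-2.75), a mitotic checkpoint kinase, Pdgfra (-2.71), a growth factor receptor of oligodendrocyte precursors, and Igfbp3 (-2.71), which binds insulin-like growth factors. Fabp7 lay between 2.99 and 4.80 in BLZ945 1, 5, 6 and 7, between 5.37 and 6.94 in BLZ945 2, 3, 4 and 8, and between 6.85 and 8.86 in Vehicle. These sets of mice come from the split of the BLZ945 mice with the most genes, described below. Fabp7 is among its 58 genes, so the parting of the sets was fixed by that choice and is no test. The largest rises were in Dpys (2.11), an enzyme of pyrimidine breakdown, Klrb1a (2.10), a lectin-like receptor of natural killer cells, Ccn3 (2.04), a matricellular protein, and Il18bp (1.87), a secreted cytokine inhibitor. Cd5 (1.85), a lymphocyte surface protein, Sh3bgr (1.74), Gpnmb (1.69), a transmembrane glycoprotein, the apolipoprotein genes Apoc1 (1.68) and Apoc4 (1.65), and Fbxo32 (1.60), a ubiquitin ligase subunit, followed. With labelled volume as a covariate in 14 mice, 15 genes passed, and volume and agent cannot be separated in a design without overlap. Within the 8 mice of 11.29 weeks 89 genes passed, 11 higher and 78 lower, with age cohort as covariate 238, and in males alone 2. With age cohort in the fit the agent difference also comes from the 8 mice of 11.29 weeks alone, as each other age held 1 agent. Quantile normalization repeated across the arrays gave 57.3% lower calls in place of 67.3%, and the array SD as covariate gave 1644 genes with 47.3% lower.

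**Figure D1:**
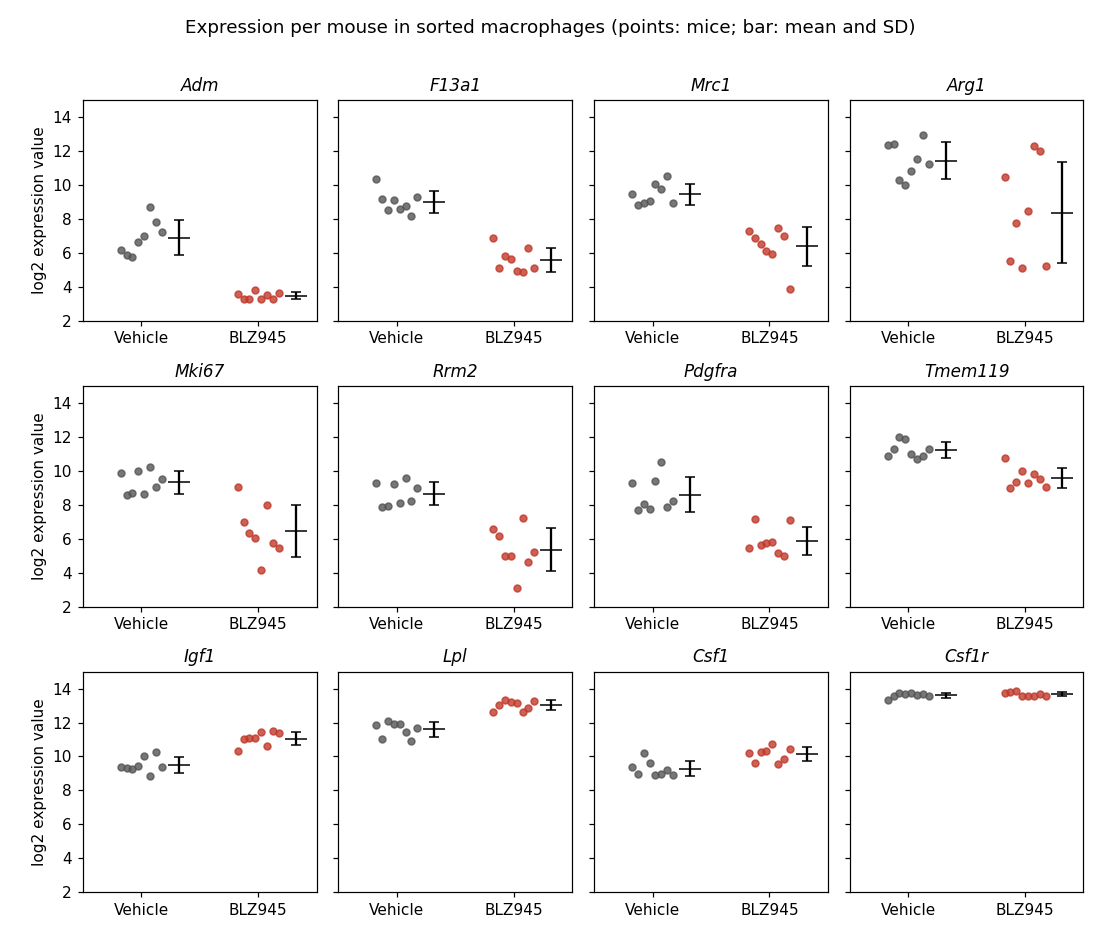
Log2 expression value (vertical axis) of 12 genes in each Vehicle mouse (grey) and BLZ945 mouse (red), with the mean and SD as a black bar, 8 mice per group. Adm lay between 3.25 and 3.81 in BLZ945 and at 5.75 or above in Vehicle, Arg1 spread from 5.10 to 12.27 in BLZ945, and Csf1r lay between 13.31 and 13.84 in all 16 mice.

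The transcript of the target did not pass. Csf1r was 13.61 ± 0.14 in Vehicle and 13.66 ± 0.12 in BLZ945, a difference of 0.06 (SE 0.09, n = 8 each, adjusted p = 0.73). These values lie close to the highest of each array, 13.87 to 14.34, where a change could be compressed, so the test of Csf1r does not exclude one. The ligand gene Csf1 rose by 0.85 (adjusted p = 0.0129), while the other ligand, Il34, differed by -0.09 (adjusted p = 0.616) near the bottom of the scale. In the list of the CSF-1 receptor family and ligands, 4 of 15 genes rose and 0 fell, and the same numbers held adjusted over the list alone. Besides Csf1 these were Ifngr2 (0.75), a chain of the interferon gamma receptor, Csf2rb2 (0.57), a cytokine receptor chain, and Csf3r (0.80), the receptor of granulocyte colony-stimulating factor. Csf2ra, a receptor chain for granulocyte-macrophage colony-stimulating factor, differed by 0.05 (adjusted p = 0.889). The list mean was 0.25 higher (exact permutation adjusted p = 0.0211), with adjusted p = 0.225 with an estimated correlation. The call of Csf3r ended without any 1 of Vehicle 1, 5, 6, 7 or 8 or BLZ945 1, 4 or 5 (adjusted p 0.0582 to 0.0737), and that of Csf2rb2 without Vehicle 4 or 8 or BLZ945 7 or 8 (0.0546 to 0.0607). Camera's call of the list CSF-1 receptor family and ligands ended without Vehicle 1, 6 or 8 or BLZ945 1 or 6 (adjusted p 0.0511 to 0.108) and with the glioma marker mean as covariate (0.34).

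Of 25 genes of alternative activation, 7 fell, 1 rose and 17 did not pass, and adjusted over the list alone 9 fell and 2 rose. Adm, F13a1 and Mrc1 were among those that fell, with Cd163, a scavenger receptor for haemoglobin, which fell from 4.69 ± 0.48 to 3.28 ± 0.29 (n = 8 each, adjusted p = 0.000171). Arg1, the arginase that competes for arginine with nitric oxide synthase, averaged 11.43 ± 1.06 in Vehicle and 8.35 ± 2.97 in BLZ945 (n = 8 each). It lay between 8.48 and 12.27 in BLZ945 1, 5, 6 and 7 and between 5.10 and 7.74 in BLZ945 2, 3, 4 and 8. Arg1 is among the genes of the split that parted these sets, so these ranges are no test. Its difference of -3.08 (SE 0.97) did not pass (adjusted p = 0.0572), and it passed without BLZ945 1 (0.0467), BLZ945 6 (0.0144) or BLZ945 7 (0.0257). BLZ945 1, 6 and 7 had the highest Arg1 of the BLZ945 mice (10.47, 12.27 and 11.98), so these passes are no test of a fall. The cytokine gene Il10 differed by 0.07 (adjusted p = 0.794). The list mean was 0.81 lower (exact permutation adjusted p = 0.0181), with adjusted p = 0.0664 with an estimated correlation, and 4 of its genes were picked by the study from these samples, so the list is not independent evidence. Of 19 monocyte-derived macrophage genes 3 fell, and their list mean differed by -0.64, with adjusted p = 0.207 with an estimated correlation, and by -0.14 in the mice of 11.29 weeks. Of 22 genes of classical activation, 1 rose and 0 fell, over the list alone too. The riser was Il1b, an inflammatory cytokine gene (1.04, adjusted p = 0.0123), and the nitric oxide synthase gene Nos2 differed by 0.16 (adjusted p = 0.575). The classical list mean differed by 0.04 (exact permutation adjusted p = 0.865).

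Of 31 cell cycle genes, 28 fell, 0 rose and 3 did not pass, and adjusted over the list alone 30 fell. Beside Rrm2, Mki67 and Bub1, these included the replication helicase subunits Mcm5 (-2.13) and Mcm6 (-1.64) and the cyclin gene Ccne2 (-2.40). The list mean went from 7.54 ± 0.53 to 5.87 ± 0.59 (n = 8 each, exact permutation adjusted p = 0.00264), lower than every Vehicle mouse in 7 of 8 BLZ945 mice. Its adjusted p with an estimated correlation was 0.0503. Of 13 glioma and oligodendrocyte precursor markers 6 fell, and their mean differed by -0.89, with adjusted p = 0.332 with an estimated correlation.

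In the hypoxia and angiogenesis list 6 of 24 genes fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. Those with the smallest p were P4ha2 (-1.82), a collagen prolyl hydroxylase subunit, Ddit4 (-1.28), a stress-induced inhibitor of growth signalling, Ldha (-0.76), the lactate dehydrogenase of glycolysis, and Ero1a (-1.11), an oxidase of the endoplasmic reticulum. The list mean fell by 0.48 (exact permutation adjusted p = 0.00264), with adjusted p = 0.137 with an estimated correlation. In the immediate early and stress list 4 of 22 genes rose and 3 fell, 9 and 3 adjusted over the list alone. The 3 that fell were the chaperone genes Hspa1b, Hspa1a (-2.13) and Hsp90aa1 (-0.73), while the transcription factor gene Jund rose by 0.75. The mean of this list differed by 0.11 (exact permutation adjusted p = 0.629). Camera called the list immediate early and stress higher without Vehicle 7 (0.0174), BLZ945 4 (0.0452) or BLZ945 8 (0.0462).

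Of 20 genes of cholesterol efflux and lipid handling, 5 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone. The cholesterol transporter genes Abcg1 and Abca1 rose by 0.81 and 0.56, the fatty acid-binding protein gene Fabp3 by 1.55 and the lysosomal lipase gene Lipa by 0.63. The list mean was 0.30 higher (exact permutation adjusted p = 0.0033), with adjusted p = 0.0938 with an estimated correlation, and its camera call was lost within the mice of 11.29 weeks (0.24, adjusted p = 0.0552). Of 16 genes of cholesterol synthesis, 4 fell and 0 rose, over the list alone too. These were Idi1 (-0.87), Sqle (-0.93), Fdps (-0.50) and Hmgcs1 (-0.64), enzymes of the sterol pathway. The call of Hmgcs1 ended without any 1 of Vehicle 1, 5, 6 or 7 or BLZ945 1, 2, 4, 5 or 7 (adjusted p 0.0513 to 0.0671), and that of Fdps without Vehicle 5, 6, 7 or 8 or BLZ945 2 or 7 (0.0517 to 0.0645). The list mean fell by 0.21 (exact permutation adjusted p = 0.018), with adjusted p = 0.124 with an estimated correlation. Camera's call of the list cholesterol synthesis ended with dim genes left out (0.0947).

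Among 18 genes described in disease-associated microglia, 6 rose and 0 fell, and 10 rose adjusted over the list alone. They included Lpl, Igf1, Gpnmb and the protease inhibitor gene Cst7, which rose by 1.39. The list mean rose from 11.36 ± 0.11 to 12.01 ± 0.24 (n = 8 each, exact permutation adjusted p = 0.00264), above every Vehicle mouse in 8 of 8 BLZ945 mice, with adjusted p = 0.0503 with an estimated correlation. Of 18 microglia identity genes, 5 fell and 1 rose, over the list alone too. The fructose transporter gene Slc2a5 (-1.79), the membrane protein gene Tmem119 (-1.64), Crybb1 (-1.50) and the purine receptor gene P2ry12 (-1.35, adjusted p = 0.00699) fell, and the fractalkine receptor gene Cx3cr1 differed by -0.42 (adjusted p = 0.259). This list's mean was 0.49 lower (exact permutation adjusted p = 0.0244), with adjusted p = 0.343 with an estimated correlation. Of 19 monocyte-derived macrophage genes, 3 fell and 0 rose, and 7 fell adjusted over the list alone. They were Tgfbi (-1.78), a secreted matrix protein, Hp (-0.83), haptoglobin, and Ccr2 (-1.65), the receptor that brings monocytes out of the marrow. The call of Ccr2 (adjusted p = 0.0484) was lost without any 1 of Vehicle 1, 2, 4, 5, 7 or 8 or BLZ945 3, 4, 5, 7 or 8 (0.0565 to 0.0945). The list mean was 0.64 lower (exact permutation adjusted p = 0.0399), with adjusted p = 0.207 with an estimated correlation. In the mice of 11.29 weeks it differed by -0.14 (adjusted p = 0.295 by camera).

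Other lists moved little as a whole. Among 17 apoptosis and survival genes, Bcl2l11, which encodes a death-promoting protein, rose by 1.22 and Casp8 fell by 0.59, with 2 higher and 2 lower adjusted over the list alone (mean 0.14, exact permutation adjusted p = 0.211). Among 19 chemokine genes, Ccl6 (0.81), Ccl4 (0.84) and Cxcl16 (0.58) rose and Pf4 (-1.57) fell, and 3 rose and 3 fell adjusted over the list alone. The call of Cxcl16 ended without Vehicle 1, 4 or 6 or BLZ945 7 (adjusted p 0.0562 to 0.0624). The chemokine mean of -0.05 and median of 0.11 differed in sign (exact permutation adjusted p = 0.695). Among 22 genes of phagocytosis and Fc receptors, the complement receptor gene C3ar1 rose by 0.72 and Itgam, which encodes the CD11b used for sorting, fell by 1.17, and 3 rose and 1 fell adjusted over the list alone. The mean of that list was -0.04 and its median 0.02 (exact permutation adjusted p = 0.629). Among 20 genes of matrix remodelling and proteases, the receptor gene Plaur (0.65) and the protease inhibitor gene Timp2 (0.51) rose, and Timp1 (-1.05) and Ctsc (-0.45) were among 4 that fell. Adjusted over the list alone 4 rose and 4 fell. The call of Timp2 ended without Vehicle 1, 2, 6 or 8 or BLZ945 3 or 7 (adjusted p 0.0504 to 0.068). This list's mean of 0.17 was positive while camera placed it lower without calling it (exact permutation adjusted p = 0.483). Serpinb2, a protease inhibitor gene of this list that the study picked, so that the list is not independent evidence, differed by 2.63 (SE 0.93, adjusted p = 0.0948) and passed without Vehicle 7 (0.0325) or BLZ945 5 (0.0393).

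Of 21 type I interferon genes and of 17 antigen presentation genes, 0 rose and 0 fell, over the lists alone too. Ifi27l2a and Ifit3, both induced by interferon, differed by -0.75 (adjusted p = 0.0611) and -0.72 (adjusted p = 0.0943). Camera at the preset correlation placed the interferon list lower, with adjusted p = 0.589 with an estimated correlation, and its mean differed by -0.42 (exact permutation adjusted p = 0.292), by -0.11 in the mice of 11.29 weeks and by -0.07 in males. Without BLZ945 6, limma called 6 of the 21 genes lower, Ifit3 with adjusted p = 0.00933 and Ifi27l2a with 0.011. BLZ945 6 was the highest BLZ945 mouse for 20 of the 21 genes, so these calls are no test. Without Vehicle 4, the lowest Vehicle mouse for both, Ifit3 and Ifi27l2a passed too (0.0384 and 0.0499). The antigen presentation genes Tapbp and H2-Eb1 differed by 0.43 (adjusted p = 0.178) and -0.74 (adjusted p = 0.338), and the list mean by -0.14 (exact permutation adjusted p = 0.701). Tapbp passed without Vehicle 2 (0.0387). The list antigen presentation was lower by camera without BLZ945 6 (-0.33, adjusted p = 0.0384). BLZ945 6 had the highest mean of this list of any mouse (11.84), so leaving it out is no test of a fall. With sex and age cohort as covariates camera placed the list higher (0.50, adjusted p = 0.00647). In that covariate fit the agent difference rests on the mice of 11.29 weeks. Both calls used the preset correlation of 0.01, while the correlation estimated for this list in the main comparison was 0.744. Neither adjusted p therefore decides on a change of the list. The tumour suppressor transcript Cdkn2a, from the locus deleted in these mice, was 3.15 ± 0.19 in Vehicle and 3.34 ± 0.23 in BLZ945 (n = 8 each, adjusted p = 0.342). At the preset correlation camera called 10 of the 17 lists, 3 higher and 7 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.0503), fry called 8, and the exact permutation of list means 9, 3 higher and 6 lower.

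**Figure D2:**
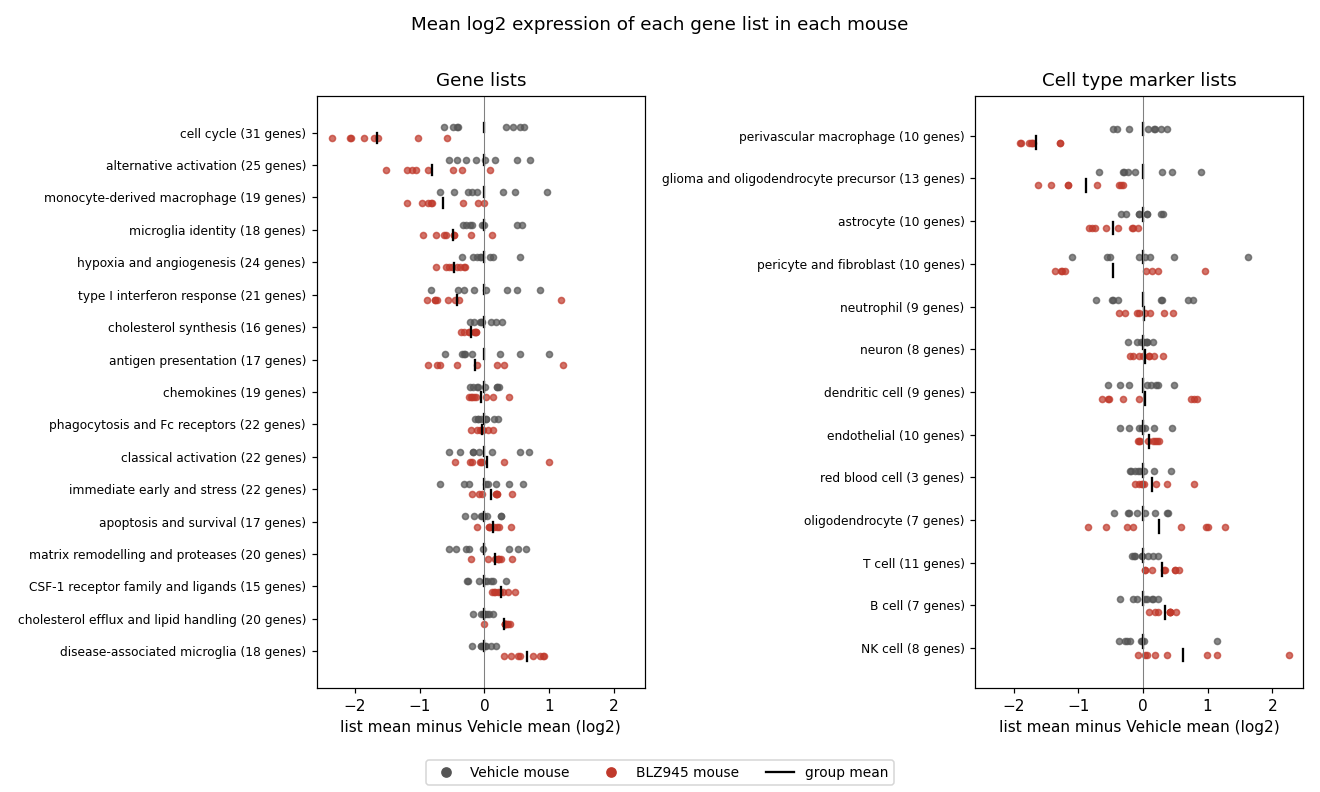
Mean log2 value of each gene list (left) and cell type marker list (right) in each Vehicle mouse (grey) and BLZ945 mouse (red), minus the Vehicle mean, with group means as black bars and 8 mice per group. The perivascular macrophage and disease-associated microglia lists separated the groups in all 16 mice, and 1 BLZ945 mouse stood above the rest in the interferon list.

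Markers of other cells that the gate could hold were measured in the same arrays. Of 10 perivascular macrophage markers, 8 fell and 0 rose, over the list alone too, and the list mean went from 7.55 ± 0.32 to 5.89 ± 0.24 (n = 8 each, exact permutation adjusted p = 0.00202). This call held with an estimated correlation (adjusted p = 0.00218). Ms4a7 fell by 1.68 and Folr2, a folate receptor gene, differed by 0.57 (adjusted p = 0.225) and passed without BLZ945 1 (0.0403). The list shares 5 genes with alternative activation, among them Mrc1 and F13a1, which the study picked, so it is not independent evidence. Of 13 glioma and oligodendrocyte precursor markers, 6 fell and 0 rose, and 7 fell adjusted over the list alone. The transcription factor gene Olig1 went from 8.66 ± 0.72 to 6.71 ± 1.13 (n = 8 each, adjusted p = 0.00685) and the proteoglycan gene Cspg4 differed by 0.44 (adjusted p = 0.424). Olig1 lay between 5.37 and 5.86 in BLZ945 1, 5, 6 and 7, between 7.32 and 8.06 in BLZ945 2, 3, 4 and 8, and between 7.51 and 9.77 in Vehicle. The list mean fell by 0.89 (exact permutation adjusted p = 0.0155), with adjusted p = 0.332 with an estimated correlation. In the same sets of mice it lay between 4.59 and 5.07, between 5.51 and 5.92, and between 5.54 and 7.12 in Vehicle. Of 10 astrocyte markers, 2 fell and 0 rose, 3 adjusted over the list alone, and Aldoc, a glycolytic enzyme gene, fell by 1.58 while the glutamate transporter gene Slc1a3 differed by -0.04 (adjusted p = 0.935). The astrocyte mean was 0.47 lower (exact permutation adjusted p = 0.0187), with adjusted p = 0.332 with an estimated correlation. It lay between 5.11 and 5.37 in BLZ945 1, 5, 6 and 7, between 5.57 and 5.87 in the other 4, and between 5.61 and 6.26 in Vehicle. These sets were parted by the split with the most genes, which holds Olig1 and other markers of both lists. The ranges in them are therefore no test. Camera's call of the list astrocyte ended without Vehicle 3, 4 or 8 or BLZ945 6 (adjusted p 0.0557 to 0.107).

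Of 11 T cell markers, 1 rose, Cd5, and 0 fell, and 5 rose and 1 fell adjusted over the list alone. The cytokine receptor gene Il7r differed by -0.85 (adjusted p = 0.0995) and passed without BLZ945 1 (0.0121). The T cell mean was 0.30 higher (exact permutation adjusted p = 0.0194). Of 7 B cell markers, 2 rose and 0 fell, over the list alone too, and the adaptor gene Blnk rose by 0.68, while Ighm differed by -0.26 (adjusted p = 0.615). The B cell mean was 0.33 higher (exact permutation adjusted p = 0.0121). Camera called neither list, at the preset or at an estimated correlation. At the preset correlation it called the list T cell without Vehicle 2 or BLZ945 3, 7 or 8 (adjusted p 0.0367 to 0.0497). Of 8 NK cell markers 0 passed, and 2 were higher adjusted over the list alone. The granzyme gene Gzma differed by 1.83 (adjusted p = 0.0506) and passed without Vehicle 2 (0.0148), BLZ945 4 (0.045), 5 (0.0485), 6 (0.0471) or 7 (0.0439), and Klrk1 by -0.65 (adjusted p = 0.404), and the list mean by 0.62 (exact permutation adjusted p = 0.155, and adjusted p = 0.627 with an estimated correlation). Camera's call of the list NK cell ended without Vehicle 3, 4, 5, 6, 7 or 8 or BLZ945 1, 2 or 6 (adjusted p 0.0522 to 0.185). In the neuron, oligodendrocyte, endothelial, pericyte and fibroblast, neutrophil, dendritic cell and red blood cell lists 0 genes passed, and the means differed by 0.03, 0.25, 0.09, -0.46, 0.02, 0.04 and 0.14 (exact permutation adjusted p from 0.493 to 0.945). Their brightest members differed by 0.49 for Mbp, 0.10 for Cnp, -0.86 for Col3a1, -0.68 for Col1a2, -0.54 for S100a8 and 0.83 for Batf3, none past the threshold. In BLZ945 1, 5, 6 and 7, Col3a1 lay between 6.56 and 7.60, below every Vehicle mouse (7.78 to 11.34), and in BLZ945 2, 3, 4 and 8 between 9.55 and 10.33. Col1a2 lay between 6.28 and 7.37 and between 8.63 and 9.71 in the same mice (Vehicle 6.59 to 10.84). Their oligodendrocyte means were 6.05 to 6.75 and 7.49 to 8.17 (Vehicle 6.45 to 7.29). Col3a1, Col1a2 and the oligodendrocyte marker Cldn11 are among the genes of the split that parted these mice, so these ranges are no test. Without Vehicle 2, Batf3 (adjusted p = 0.0294) and the endothelial gene Flt1 (0.047) passed. Camera called the list pericyte and fibroblast lower without Vehicle 2 or BLZ945 2 or 8 (adjusted p 0.0177 to 0.0436).

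Within the 8 mice of 11.29 weeks, list means differed by -1.36 for cell cycle, -0.55 for alternative activation, -0.36 for microglia identity, -0.68 for hypoxia and angiogenesis, 0.48 for disease-associated microglia, 0.27 for the CSF-1 receptor family and -0.11 for type I interferon. Those of the perivascular, glioma and astrocyte markers differed by -1.86, -0.95 and -0.39, and those of the NK, T and B cell markers by 1.35, 0.42 and 0.42. The means of antigen presentation (0.33), matrix remodelling (-0.02) and immediate early genes (-0.02) had the opposite sign there to that in all mice. Among single genes in the mice aged 11.29 weeks only, Ccr2 differed by -0.33, Gpnmb by 0.99 and Mki67 by -1.88 (adjusted p = 0.717, 0.156 and 0.17). Camera called the list dendritic cell higher in these mice (0.63, adjusted p = 0.00321).

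The second comparison checked the labelled sexes and asked whether sex marked other genes. Female mice had higher Xist, the RNA that silences an X chromosome, at 12.01 against 4.56 in males, a difference of 7.41. The Y-linked genes Eif2s3y (-5.82), Kdm5d (-3.29) and Uty (-1.46) were lower in females. Xist lay at 11.74 or above in 9 of 9 female mice and at 5.11 or below in 7 of 7 males, as labelled. These 4 genes were the ones that passed among 12394, with 1214 at an unadjusted p under 0.05. Tuba8 (-1.09, adjusted p = 0.0928), Kctd20 (-0.61), Eif2s3x (0.75), Rxrg (0.59), Pbdc1 (0.50) and Cd209g (0.51) came next and did not pass. Without Vehicle 4, 14 genes passed, and without any 1 other mouse 3 to 6. The change with BLZ945 differed by sex in 0 genes by limma, with 414 at an unadjusted p under 0.05 and a smallest adjusted p of 0.983. The leading genes were Oxa1l (1.00), Akap10 (0.92) and Aste1 (0.97), as female minus male effect.

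The third comparison set 4 older BLZ945 mice, of 13.14 weeks, against 4 of 11.29 weeks. In the older mice 5 genes were lower and 0 higher, with 2312 at an unadjusted p under 0.05. They were Cntrl (-1.49, adjusted p = 0.0195), a centriole protein gene, the chemokine receptor gene Ccr7 (-1.54, 0.0195), the tight junction gene Cldn1 (-1.73, 0.0224), Cd55 (-1.46, 0.0325), which encodes a complement regulator, and Gnl2 (-1.26, 0.0473). Cd55 and Gnl2 were outside the rule for named genes and were added after their values were seen. The count was 0 without BLZ945 1, 2, 4 or 5, 2 without BLZ945 6 or 8, 13 without BLZ945 7 and 16 without BLZ945 3. The labels do not say whether the ages stand for litters or sort days.

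The fourth comparison related expression to labelled initial tumour volume within the 8 BLZ945 mice. By limma 0 genes passed, with 846 at an unadjusted p under 0.05 and a smallest adjusted p of 0.653. Per doubling of volume, Cdo1, an enzyme gene of cysteine breakdown, had a slope of 1.4, Crybb1 of -1.08 and the actin regulator gene Coro1a of -0.88.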

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

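The comparisons with other splits of the mice were planned, and the covariate tests of the 3 patterns below, among them that of a share of other cells that differs between mice, the test of a purer sort by cell type, the genes and ranges of the split with 58 genes, the interferon list without 1 mouse and the test of unnamed probe sets were chosen after gene results had been seen. Among 100 splits of the 16 mice, 1, the real one, gave as many as 984 changed genes and the highest other gave 580. Chance is thus unlikely for that count, as far as 100 splits can tell. The split with 580 genes had a difference in array SD of 0.0855, against 0.0587 for the real one. At least 10 gene lists were called by camera in 7 of 100 splits, with 11 as the highest other, so chance cannot be excluded for the number of lists. The other splits had a median of 5 called lists, and 59 of them had 5 or more. For sex, 1 of 100 relabellings gave 4 genes and the highest other 1, so chance is unlikely. For the interaction of agent and sex, 100 of 100 gave at least the real count of 0. The highest other gave 1760, which points to a structure of the samples. It was the 1 relabelling of 100 with over 100 genes and ranked 1 for the size of the array SD interaction (0.183, against 0.0608 for the real sexes), and the cause was not tested. For age within BLZ945, 2 of 35 splits gave at least 5 genes and the highest other 58, so chance cannot be excluded. The split with 58 genes points to a structure of the samples. It set BLZ945 1, 5, 6 and 7 against 2, 3, 4 and 8, with an array SD difference of 0.0298, against 0.0989 for the real split. In BLZ945 1, 5, 6 and 7, 56 of these genes were lower, Nid1, Pdgfrb and Col3a1 with the smallest p, and 2 were higher, Arg1 and Tgm2. The means of the pericyte and fibroblast markers were 5.52 to 5.68 in these mice against 6.93 to 7.85 in the other 4, those of the oligodendrocyte markers 6.05 to 6.75 against 7.49 to 8.17, and those of the astrocyte markers 5.11 to 5.37 against 5.57 to 5.87. Arg1 lay the other way, at 8.48 to 12.27 against 5.10 to 7.74.

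Cell cycle genes were lower in BLZ945, by 1.67 on average (list mean -1.67, 95% interval -2.22 to -1.11). With the mean of the glioma and oligodendrocyte precursor markers as covariate the difference was -1.53 (-2.35 to -0.72). Within groups the 2 means were hardly related (r = 0.14, permutation p = 0.62), with r = 0.53 in Vehicle and -0.20 in BLZ945. The adjustment could therefore hardly move the difference and does not decide on less RNA from glioma cells, which stays open. The cell cycle mean lay at 5.17 to 6.95 in BLZ945 1, 5, 6 and 7 and at 5.46 to 5.90 in the other 4, where glioma markers were higher, against 6.90 to 8.15 in Vehicle. The difference was -1.63 with array SD as covariate and -1.63 with the 3' to 5' difference of control probe sets. Within groups neither was clearly related to the cell cycle mean (r = 0.08 and -0.13, permutation p = 0.77 and 0.67). These adjustments too could hardly move the difference and do not decide on array spread or RNA degradation. Less division of the macrophages themselves is a hypothesis that stays open, and so does the labelled tumour volume, since with it as covariate 15 genes passed and it cannot be told apart from the agent where 0 volumes overlap.

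Alternative activation genes were lower in BLZ945 (list mean -0.81, 95% interval -1.30 to -0.33). The difference was -0.72 with array SD as covariate and -0.86 with the 3' to 5' difference of control probe sets. Within groups neither was clearly related to this list's mean (r = 0.25 and 0.17, permutation p = 0.37 and 0.58). Both could thus hardly move the difference and do not decide on array spread or RNA degradation. With the mean of the monocyte-derived macrophage genes as covariate the difference was -0.33 (-0.74 to 0.08), so a smaller share of such cells may contribute and stays open. Within groups both means had r = 0.76 (permutation p = 0.00076, adjusted 0.00114) and rho = 0.77 (permutation p = 0.00107, adjusted 0.00161) over 16 mice, and r = 0.68 without the 2 farthest. The perivascular macrophage markers fell as well (list mean -1.66, below every Vehicle mouse in 8 of 8 BLZ945 mice). They share Mrc1, Cd163, F13a1, Folr2 and Lyve1 with this list, so they cannot tell fewer such cells from lower expression. A smaller share of these cells was not tested and stays open. A change of state within the cells stays open too, as does labelled tumour volume, which cannot be told apart from the agent.

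Glioma and oligodendrocyte precursor markers were lower in BLZ945 (list mean -0.89, 95% interval -1.40 to -0.37) in cells sorted on CD11b, at 4.59 to 5.07 in BLZ945 1, 5, 6 and 7 and 5.51 to 5.92 in the other 4, against 5.54 to 7.12 in Vehicle. With an unchanged mix of the other cells in the digest, a purer sort would lower the markers of every other type alike. Bright oligodendrocyte (6 of 7) and endothelial markers (7 of 10) moved apart from the glioma markers, by 1.15 (0.63 to 1.68) and 0.96 (0.40 to 1.51). The exact two-sided permutation adjusted p was 0.00311 and 0.00746. This argues against a purer sort as the whole cause only if the mix stayed the same, which was not tested. Bright astrocyte markers (6 of 10, change -0.63, -1.02 to -0.25) and pericyte and fibroblast markers (9 of 10, change -0.49, -1.51 to 0.53) lay no further from the glioma markers than their spread, and neuron markers were too dim to test, so a test pooled over types was dropped. With array SD as covariate the difference was -0.85. Within groups array SD was hardly related to the glioma marker mean (r = 0.09, permutation p = 0.76). It could thus hardly move the difference and does not decide on the spread of the array values. With the mean of the oligodendrocyte and the pericyte and fibroblast markers as covariate the difference was -0.82 (-1.15 to -0.50). That covariate averages list means that differed by 0.25 and -0.46 between the agents, so it could hardly move the difference. It does not decide on a share of other cells that differs between mice. Such a share stays open. Glioma, astrocyte, oligodendrocyte and pericyte markers were all lower in BLZ945 1, 5, 6 and 7 than in the other 4 BLZ945 mice. That is no test, as these mice were parted by the split with the most genes, and 10 of its 58 genes are in marker lists. Oligodendrocyte markers of BLZ945 1, 5, 6 and 7 overlapped with Vehicle (6.05 to 6.75 against 6.45 to 7.29). Less RNA of glioma cells and astrocytes together, in the digest or taken up by the macrophages, stays open too and was not tested.

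Single mice stood apart in 14 of 222 groups of 8 tested, where chance flags about 5% of groups. BLZ945 6 had a type I interferon list mean of 9.33, against 7.27 to 7.76 in the other BLZ945 mice, and was the highest of them for 20 of 21 members. The list mean differed by -0.42 in all mice (exact two-sided permutation p = 0.189) and by -0.65 without BLZ945 6, which is no test, as this mouse was left out for its value in the same list. The same mouse had 9.23 for Ifit3 (others 7.36 to 8.08) and 7.35 for Hspa1b (others 5.86 to 6.37). BLZ945 8 had 3.85 for Mrc1 (others 5.94 to 7.46). BLZ945 1 had 11.35 for Tgfbi (others 9.39 to 10.32) and 8.37 for the cholesterol efflux list (others 8.69 to 8.77). BLZ945 2 had 9.75 for Cxcl16 (others 10.26 to 10.63) and 7.93 for Csf2ra (others 8.58 to 8.82). BLZ945 7 had 12.02 for C3ar1 (others 11.17 to 11.43), and BLZ945 5 had 3.91 for Il10 (others 2.79 to 3.32). In Vehicle, mouse 7 had 4.45 for Ccn3 (others 2.88 to 3.34), mouse 1 had 13.31 for Csf1r (others 13.54 to 13.73), and mouse 2 had 11.88 for Abca1 (others 12.47 to 12.68). Vehicle 2 also had an NK cell list mean of 5.61 (others 4.09 to 4.48).

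Probe sets with no gene name in the annotation used here were outside the comparisons. Of 1555 tested by limma, 71 changed, 20 higher and 51 lower in BLZ945. Of 691 probe sets with several gene names, 64 changed.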

How the results depend on the processing

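The alternatives with array SD, the 3' to 5' difference, the glioma marker mean, 6 or 10 arrays, the oligodendrocyte and pericyte marker mean, BLZ945 4 and 5, 1, 5, 6 and 7, or 2, 3, 4 and 8 left out and the exact permutation were chosen after the data were seen. The 984 changed genes stayed within 1.5 times with dim genes left out (1007), probe sets averaged (932), quantile normalization again (1142, 488 higher and 654 lower), centring (986), trend and robust eBayes (982), array weights (1257), sex as covariate (1065), mice with a labelled volume (951), a plain test (871), the 3' to 5' difference (1104), 10 arrays (685), BLZ945 4 and 5 left out (692) and the oligodendrocyte and pericyte marker mean (1143, 979 shared). Vehicle and BLZ945 mice share only numbers: 5 of 8 same-numbered pairs had r over 0.1 (-0.48 to 0.39) and 2 BLZ945 arrays correlated best with their own number. With a replicate block 873 genes changed (778 shared), 265 at least 2-fold, and 11 gene lists and 4 marker lists were called.

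Changed genes numbered 1521 with every probe set tested (more probe sets), 15 with initial tumour volume, 1644 with array SD and 251 with the glioma marker mean. They numbered 238 with age cohort as covariate and 355 with sex and age cohort. In both cohort fits the agent difference rests on the mice of 11.29 weeks, the 1 age with both agents, so these counts are not separate from that subset. With fewer samples the changed genes were 89 in mice of 11.29 weeks (84 shared), 393 in females, 2 in males, 33 in the 6 widest arrays, 484 with BLZ945 1, 5, 6 and 7 left out (408 shared) and 487 with 2, 3, 4 and 8 left out (412 shared). The 273 genes of at least 2-fold became 165 with age cohort, 15 with volume, 70 at 11.29 weeks, 2 in males and 29 in the 6 widest arrays. Of 10 gene lists 0 were called with an estimated correlation, and of 4 marker lists 1. Marker lists numbered 2 with dim genes left out (fewer genes) and 7 with sex and age cohort or with BLZ945 2, 3, 4 and 8 left out. Genes differing by sex were 10 with every probe set. They were 0 with named X and Y genes left out, which removes the 4 genes that passed. Genes differing by age were 3 with dim genes left out. Where no reason is given, the cause was not tested.

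With volume as covariate, the direction reversed for Apoc4 (-0.017), Fbxo32 (-0.67), Tmem119 (0.11), Crybb1 (0.45), Csf2rb2 (-0.51), C3ar1 (-0.15) and Timp2 (-0.11), none of them called. The list antigen presentation reversed to 0.50 with sex and age cohort, a fit whose agent difference rests on the mice of 11.29 weeks. The list pericyte and fibroblast reversed to 0.78 with the glioma marker mean, and the list oligodendrocyte to -0.46 with BLZ945 2, 3, 4 and 8 left out. For these the cause was not tested. Of 70 called named genes, 70 kept their call with the oligodendrocyte and pericyte marker mean, 69 with the replicate block, 67 with array SD, 36 with age cohort, 17 at 11.29 weeks and 3 with volume. Arg1 passed with the replicate block (0.0261), dim genes left out (0.0481), the glioma marker mean (0.00633), the oligodendrocyte and pericyte marker mean (0.00879) and in females (0.0342). Leaving out BLZ945 1, 5, 6 and 7 or 2, 3, 4 and 8 is no test of Arg1 or of these markers, whose values part these mice.

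Leaving out 1 mouse each, changed genes ranged from 710 (without Vehicle 6) to 1188 (without BLZ945 6), those of at least 2-fold from 243 to 310, gene lists from 9 to 11 and marker lists from 2 (without Vehicle 3, 4 or 8 or BLZ945 6) to 6 (without Vehicle 2 or BLZ945 8). Genes differing by sex ranged from 3 to 14 and by age from 0 to 16, and the interaction and volume fits gave 0 throughout. No background signal was analysed here, so dim genes could not be judged.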

Other observations

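The genes and the test of symbol families below were chosen after their values were seen. Among changed genes outside the fixed lists, Cd93, a receptor of myeloid and endothelial cells, fell by 2.54 (adjusted p = 1.54e-05) and the chemokine receptor gene Ccr1 by 2.38 (adjusted p = 0.00112). The interferon-induced membrane protein gene Ifitm1 (-2.37) and the cyclin gene Ccnd1 (-1.79) fell too. The secreted kinase gene Fam20c rose by 1.48, the prostaglandin receptor gene Ptger4 by 1.27, the activation marker Cd83 by 1.19, the transcription factor gene Mitf by 1.07 and the lysosomal protease gene Ctsf by 1.07.

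Genes were also grouped by the stem of their symbols, which gave 221 families of at least 8 genes and 442 tests. The Mcm family of replication helicase genes was the 1 enriched, with 7 of 9 genes lower (adjusted p = 1.74e-05). The proteasome stem Psma had 4 of 8 lower (adjusted p = 0.105), the stem Csf 3 of 8 higher (Csf1, Csf2rb2 and Csf3r, adjusted p = 0.13) and the kinesin stem Kif 6 of 24 lower (adjusted p = 0.148), which did not pass.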
